A study of Mus musculus with 24 samples.

How the data were processed

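Droplet single-cell libraries for gene expression, hashtags and T cell receptors were made from 8 lanes of 1 pool of cells from 8 mice, per the labels, and the 24 libraries were grouped by library type (8 each). The files used here are text lists: the cell barcodes, the features and the hashtags as deposited. They hold no measured values, and no column of values per sample was used. The submitters' processing notes name Cell Ranger 7.1.0, Seurat 4.4.1 and the genome build mm10. Which settings were used, including how cells were called and whether intronic reads were counted, is not given in the sources used here. The file name of the barcode list describes it as filtered.

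The test of SPF against GF expression that had been fixed before the data were examined (counts summed per mouse) was not run, because no expression or hashtag counts were analysed here. The number after each barcode was read as the GEM well. It is not tied to a labelled lane, and the 8 wells hold parts of 1 pool, so they are not replicates of a condition and are given as single values with range and median.

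Equal numbers of barcodes per well were tested with 100000 multinomial draws. Recovered shares divide barcodes by the cells loaded according to the labels, with exact Clopper-Pearson intervals at 95%. For each pair of wells, shared sequences were compared with the product of the well sizes divided by a set size estimated from the other pairs. The spread over pairs was compared with 1000 simulated draws, and each pair was tested with a two-sided exact hypergeometric test with Benjamini-Hochberg adjustment over 28 pairs. The hypergeometric test was added after a trial on simulated data, in which p-values taken from the draws were too coarse to pass the adjustment. Pairs of barcodes 1 base apart were counted as planned, and pairs 2 bases apart were tested with 1000 permutations of the well numbers. A threshold of 0.05 was used.

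The statistics were tested on sets of 89077 barcodes with known answers, a size given before any copies were added. A well raised by 10% was called, and equal wells were not. When 200 sequences were copied from well 1 to well 2, 1 pair was called, and 0 without copying. The copies outnumber the 172 shared sequences expected for these wells in the data. Smaller numbers were not tried, so the test may miss less crossing between wells. For barcodes 2 bases apart, the listed sequences were kept, their well numbers were shuffled, and copies with 2 changed bases were added. An addition of 500 copies in their own wells was called, and an addition of 200 was not, in 1 data set of each size.

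Genes were matched to GENCODE M21 (GRCm38) by Ensembl identifier without version, and positions are 1-based. The annotation release used by the authors is not given in the sources used here. Named genes are those of the sort gate, Tbx21, Il10, Foxp3 and Gata3, from a rule fixed before the data were examined together with the gene lists. One further gene under that rule is not reported here. Overlap between listed genes was computed from merged exons. Shares of a whole gene, and the count with introns included, used the span from gene start to gene end instead. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.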

Results

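The series profiled CD4 T cells sorted from the small intestinal lamina propria of 8 T-bet-ZsGreen mice, of which 4 were specific-pathogen-free (SPF) and 4 were germ-free (GF). These animals carry a fluorescent reporter for T-bet, the transcription factor encoded by Tbx21 that directs type 1 helper T cells. Cells of each mouse were marked with a hashtag, an antibody carrying a DNA tag, and then pooled. The pool was loaded on 8 lanes of a droplet instrument, and each lane gave a gene expression, a hashtag and a T cell receptor library, for 24 libraries. The data examined here were the list of cell barcodes, the list of measured features and the list of hashtags. Expression values, hashtag counts and receptor sequences were not analysed here, so no gene, cell type or cell share was compared between SPF and GF mice, and no depth per cell is given.

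The central comparison of the design is between SPF and GF animals, and the hashtag list gives its layout. Of the 8 hashtags, 4 were named for GF and 4 for SPF animals. Each name also carried the letter M or F, which the list does not spell out, and each combination of status and letter held 2 hashtags. Status and letter were therefore balanced, and every lane held all the animals according to the labels, so lane was not confounded with status. A single value compared between 4 and 4 mice can be assigned in 70 ways, and the smallest two-sided p of an exact permutation test is 0.029. When assignments are exchanged only within the letter there are 36, and the smallest two-sided p of that exact permutation test is 0.056.

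The hashtag sequences were 15 bases long. Over the 28 pairs the number of differing positions ranged from 7 to 14, with a median of 12. The closest pair was GF_F_rep2 (TATGCTGCCACGGTA) and SPF_F_rep1 (GAGTCTGCCAGTATC), which differed at 7 positions and belong to opposite status groups. No test applies to this property of the tags.

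The feature list held 32285 genes and the 8 hashtags, with the same identifiers and names as the hashtag list. Of the genes, 32158 (99.6%) had an entry under the same Ensembl identifier in GENCODE M21, an annotation of the mouse assembly GRCm38, which is also called mm10. The matched genes comprised 21625 protein-coding genes, 5605 lincRNA genes and 2955 antisense genes. They also included 270 T cell receptor entries and 427 immunoglobulin entries. These totals count constant genes and pseudogenes, among them 34 pseudogenes of T cell receptor V segments and 158 of immunoglobulin V segments. There were 13 mitochondrial genes by symbol. A total of 38 symbols stood on more than 1 row, on 78 rows together, and none of the list members described next was among them.

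The genes of the sort gate and the genes chosen here for the T helper subsets were all among the listed features. All 80 distinct members of the 14 gene lists had a row. These lists covered the 5 genes of the sort gate, 18 genes of type 1 regulatory (Tr1) cells, 8 of Th1, 7 of Th17, 6 of regulatory T, 4 of follicular helper and 5 of Th2 cells, and 6 of naive or central memory cells. They also covered cells that the gate should exclude or that could be carried over, with 2 genes of CD8 T cells, 5 of B or plasma cells, 4 of myeloid cells and 4 of epithelial cells. The remaining lists held 3 genes of NKT or gamma-delta T cells and 3 of cycling cells. A row shows that a gene was in the counted annotation and says nothing of its expression. A search of the feature names used here for ZsGreen matched 0 rows, and the reporter transcript was not analysed.

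The genes of the sort gate lie on 3 chromosomes in GRCm38. Ptprc (ENSMUSG00000026395), which encodes the leukocyte antigen CD45, spans chromosome 1 from 138062861 to 138175708 on the minus strand. Thy1 (ENSMUSG00000032011), which encodes CD90, spans chromosome 9 from 44043384 to 44048579 on the plus strand. The beta chain constant genes of the T cell receptor are neighbours on the plus strand of chromosome 6, with Trbc1 (ENSMUSG00000076490) at 41538218 to 41539881 and Trbc2 (ENSMUSG00000076498) at 41546730 to 41548352. These genes are closely related copies, and their sequences were not compared here. Reads from any stretch that they share could be split or lost by gene counting. Cd4 (ENSMUSG00000023274), the co-receptor of helper T cells, spans chromosome 6 from 124864692 to 124888221 on the minus strand.

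The genes named here for T helper subsets are spread over 4 chromosomes. Tbx21 (ENSMUSG00000001444) lies on chromosome 11 from 97098071 to 97115331 on the minus strand. Il10 (ENSMUSG00000016529), which encodes the suppressive cytokine made by Tr1 cells, lies on chromosome 1 from 131019845 to 131024974 on the plus strand. Foxp3 (ENSMUSG00000039521), the lineage factor of regulatory T cells, lies on chromosome X from 7573644 to 7595245 on the plus strand, and Flicr, a listed gene on the same strand, covers 18.6% of its exonic bases. Gata3 (ENSMUSG00000015619), the lineage factor of Th2 cells, lies on chromosome 2 from 9857078 to 9890034 on the minus strand, and 9230102O04Rik on the same strand covers 1.94% of its exonic bases.

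The barcode list held 89077 cell barcodes, each a sequence of 16 bases followed by a number from 1 to 8 that marks the GEM well, the droplet reaction it came from. The numbers are not tied to the labelled lanes by the sources used here, so values are given per well. Well 1 held 11557 barcodes, well 2 held 10677, well 3 held 10774, well 4 held 11165, well 5 held 10702, well 6 held 10990, well 7 held 11276 and well 8 held 11936. The median was 11077.5. The highest well exceeded the lowest by 11.8%, and the spread between wells had a coefficient of variation of 4.00% where counting error alone would give 0.948%. Equal numbers per well were rejected by a Monte Carlo multinomial test with 100000 simulated draws (chi-square 125 against an average of 7 for equal wells, p = 1e-05, the smallest these draws can give). This test sets the wells against counting error only, and with so many barcodes per well even small differences in loading or cell calling would be enough to reject equality.

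**Figure D1:**
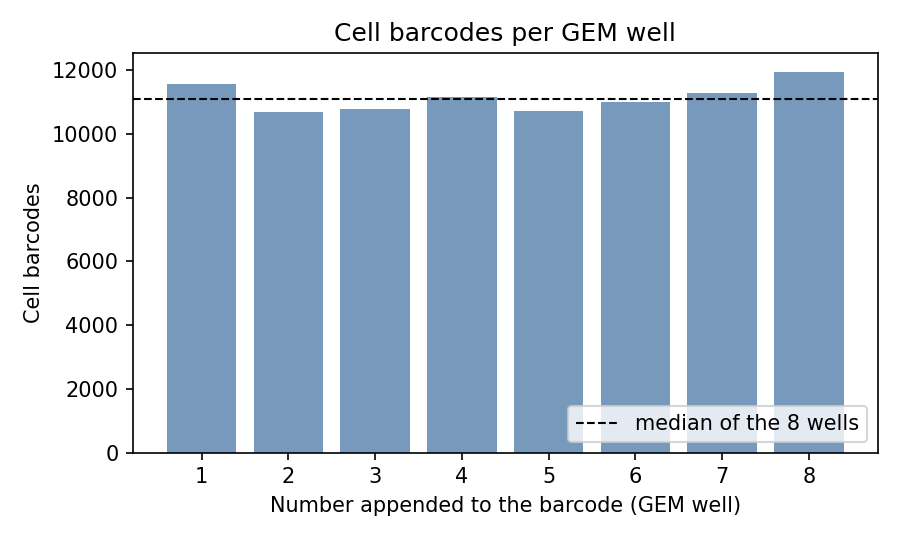
Bars give the number of cell barcodes (vertical axis, starting at 0) for each of the 8 GEM wells (horizontal axis), and the dashed line is the median of the wells, 11077.5. Counts run from 10677 in well 2 to 11936 in well 8.

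With 32000 cells loaded per lane, or 256000 in all, the barcodes amounted to 34.8% of the loaded cells (exact Clopper-Pearson 95% interval 34.6% to 35.0%). The share was lowest in well 2 at 33.4% (32.8% to 33.9%) and highest in well 8 at 37.3% (36.8% to 37.8%). These intervals cover counting error only, and take the loaded number as exact. A barcode here is a droplet called as a cell. Droplets with more than 1 cell were neither identified nor removed for the counts given here. Whether the submitters had removed any from the list is not known here.

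Different wells can hold the same barcode sequence by chance, since all draw on one set of barcodes, so each pair of wells was compared with the level common to the other pairs. The 89077 barcodes held 84365 distinct sequences, of which 79796 occurred in 1 well, 4430 in 2 wells and 139 in 3 or more. Simulated draws used a set of 714291 sequences, a size estimated from the sharing itself, so the overall level of sharing was fitted and is not tested. They gave an average of 143 sequences in 3 or more wells (95% of simulations 120 to 167). Across the 28 pairs of wells, shared sequences numbered 150 to 194, which is 0.817 to 1.13 times the expectation from the other pairs. The pairs did not differ by more than simulated draws (chi-square statistic over pairs, p = 0.59 from 1000 simulated draws). By exact hypergeometric tests, 0 of 28 pairs passed an adjusted p of 0.05 and 1 had an unadjusted p under 0.05, wells 1 and 7, which shared fewer sequences than expected (150, adjusted p = 0.30).

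**Figure D2:**
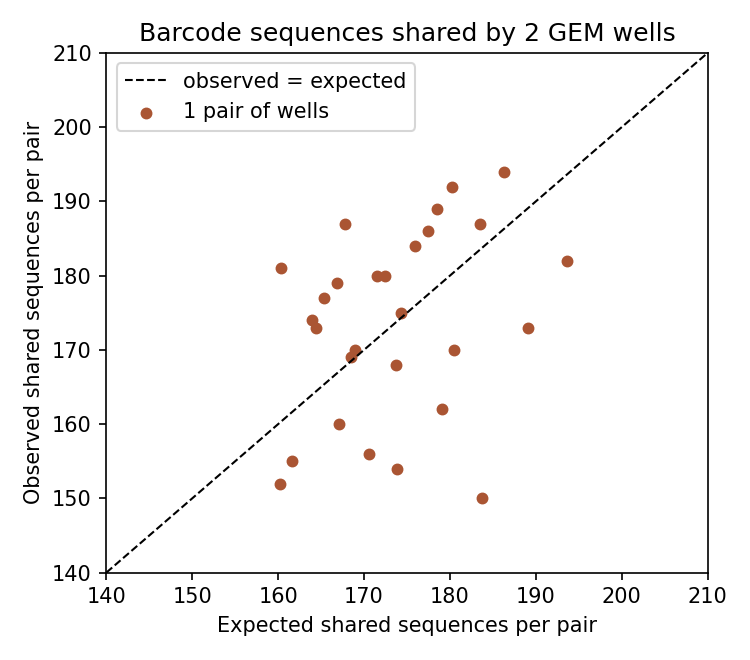
Each point is 1 of the 28 pairs of wells, with the expected number of shared barcode sequences on the horizontal axis and the observed number on the vertical axis. Neither axis starts at 0. The points scatter on both sides of the dashed line of equality, and the lowest is the pair of wells 1 and 7 with 150 shared sequences.

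No 2 barcodes in the list differed at exactly 1 base, within a well or between wells. Since 0 pairs were found between wells as well as within, this count does not test for barcodes made by sequencing errors. At 2 bases apart there were 75255 pairs, of which 9400 lay within a well. Permuting the well numbers gave an average of 9420 such pairs (95% of permutations 9250 to 9607), and the observed number did not differ from it (two-sided permutation test, p = 0.85).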

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

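The ratio of the highest to the lowest well, 1.12, was 1.08 without well 8, 1.12 without well 2 and 1.12 without sequences found in more than 1 well. Leaving out any of the other wells cannot change this ratio, and leaving out barcodes 1 base from another in their well removed none. The simulated p of the multinomial chi-square test was at its floor of 1e-05 under each setting, so it cannot show a weaker result. The recovered share of 34.8% became 31.2% without sequences found in more than 1 well, because that setting discards barcodes, and lay between 34.4% and 35.0% with 1 well left out. The spread of sharing over pairs of wells did not pass the threshold with any well left out (chi-square statistic, simulated p from 0.34 to 0.84). The count of near-identical barcodes within a well rose from 0 to 9400 when 2 bases were allowed, by construction. The ratio of those pairs to permuted wells lay between 0.992 and 1.00 with 1 well left out, an alternative chosen after seeing the data (permutation p from 0.49 to 0.96). The smallest distance between hashtags was 7 under edit distance too. The closest pair was then not unique, since pairs such as GF_M_rep2 and SPF_F_rep1 also stood at 7. All 80 list members also matched without regard to letter case. No paired analysis was possible because lane numbers mark libraries of the same pool and no values per library were compared.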

Other observations

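Some members of the gene lists have exons that overlap those of other listed genes, about as often as matched genes in general. The shares below are of annotated bases and not of reads. Whether the overlaps affected any count was not tested. All tests in this part were chosen after the lists had been seen. Of the 80 list members, 2 (2.50%) have exons that overlap those of another listed gene on the same strand, against 2.50% of the 32158 matched genes (two-sided Fisher's exact test against the other genes, p = 1.0). Foxp3 is one of them: exons of Flicr (ENSMUSG00000039545, chromosome X, 7573600 to 7581027 in GRCm38) cover 853 of its 4577 exonic bases. The span of Flicr with introns covers 34.2% of the span of Foxp3. Gata3 is the other: exons of 9230102O04Rik (ENSMUSG00000079602, chromosome 2, 9883041 to 9889540) cover 77 of its 3978 exonic bases. The span of 9230102O04Rik with introns covers 19.7% of the span of Gata3. With introns included, 3 of the 80 overlap a gene on the same strand, and the third is Ikzf2, which encodes Helios and contains Gm29112 and Gm28112. The share of matched genes with such an overlap was not computed, so this count has no background to be set against.

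On the opposite strand, 19 of the 80 members (23.8%) overlap an exon of another listed gene, against 22.6% of the matched genes (two-sided Fisher's exact test against the other genes, p = 0.79). The largest share is in Il12rb2, a receptor chain for interleukin 12, where Serbp1 covers 40.0% of the exonic bases. For Tnfrsf18, which encodes GITR, Gm16008 covers 27.2%, for Il5 Gm12214 covers 27.1%, and for Sh2d1a Tenm1 covers 26.6%. Such reads are told apart only by strand, and the strand setting of the counting is not given in the sources used here.

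If all 8 mice contributed equally, 12.5% of droplets holding 2 cells would carry both from the same mouse and so a single hashtag, which is arithmetic on the design and not a measurement.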
